A study of Homo sapiens with 36 samples.

How the data were processed

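Total RNA from NB4 cells was measured on Illumina Sentrix Human-6 BeadChips, 36 arrays in 12 groups of 3 (control, ATRA, atorvastatin and both agents, each at 8, 24 and 48 h). The series text states that the 3 arrays of a group come from independent experiments on different days. Experiments were told apart by the numbers in the sample titles, in runs of 12, and doses and chips are not given in the files used here. The authors averaged the beads of each probe in BeadStudio 1.3.1.5 without background correction, and the deposited values per array are intensity on a linear scale, not normalized between arrays. The authors' own table, used only as an alternative, holds log2 values: its 36 columns each correlated best with their own array, its column medians ran from 6.68 to 6.69, and it was not centred. No pair of arrays was identical, and 2 arrays of a group had a Pearson r of 0.965 to 0.993 across the 15308 genes tested, after normalization.

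The 47293 probes were background corrected with normexp on the signals alone (offset 50) and quantile normalized in limma 3.58.1 under R 4.3.3, because the files used here hold no detection value for the planned negative-control method. Probes above their own array's median on at least 3 arrays were kept (41648). Of all probes 18468 carry 1 gene symbol and 28825 none. The brightest probe stood for each gene, which gave 15308 genes from 17227 named probes, 1439 of the genes with several probes. NCF1 has near-identical pseudogenes, and CCL3 and CCL3L1 share sequence, so their probes may read more than 1 transcript. Other probes of ADGRE5, ASS1, BCL11A, BCL2, CD79A, CDKN1A, HK1, PHACTR3 and REPIN1, near background, gave changes between -0.53 (BCL11A) and 0.38 (PHACTR3), against changes between -2.62 and 2.38 for the probes used. For genes whose signals sit near background, an array cannot tell a low level from absence.

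A model of the 12 group means was fitted to all 36 arrays with limma (24 residual degrees of freedom), and each of 18 contrasts, 6 at each of 3 times, was tested two-sided with Benjamini-Hochberg adjustment over the 15308 genes of that contrast at 0.05. Adjusted p values in the text are from this test for genes and, for lists, from camera with Benjamini-Hochberg adjustment over all 378 tests (21 lists in 18 contrasts). Tests of the lists in control cells over time were adjusted over their own 42. At the preset correlation of 0.01, 142 of the list tests passed, and 63 of them also with an estimated correlation. The lists hold 409 genes, 362 of them measured. 1 of the 21 lists is not reported here. The other 20 cover retinoid response, granulocyte maturation, azurophil granule, monocyte and macrophage, interferon response, chemokines and inflammatory cytokines, coagulation and fibrinolysis, cholesterol synthesis and uptake, cholesterol efflux and LXR targets, fatty acid synthesis, glycolysis, immediate early and KLF, MYC and ribosome biogenesis, cell cycle, apoptosis regulators, heat shock and oxidative stress, integrated stress and unfolded protein response, and lymphoid, erythroid and epithelial and stromal markers of other cell types.

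Genes named in the report come from a rule: in each contrast the 5 largest rises and 5 largest falls among genes past the threshold whose 3 arrays of 1 group all lie above the 3 of the other (in the interaction without that last condition), up to 3 rising and 3 falling members of each list, and genes of retinoid, statin and granulocyte biology chosen in advance. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. By chance, 10% of genes show such a separation between groups of 3.

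Alternatives were no background correction, median scaling, the authors' log2 values, no filter on dim probes, the mean over a gene's probes, only the arrays of 1 time, each array and each experiment left out, the experiment as a block, and an estimated correlation for the lists. Added after the data were seen were median scaling for the lists, leaving out the 2 doubted libraries (with and without the block), a random block of experiment by ATRA arm, and an interquartile range of at least 0.2. The method was tested on simulated data: of genes given a true log2 change of 0.5, 1 or 2 in ATRA against control at 48 h, 35.8%, 97.0% and 98.5% were called, with 10 false among 164 calls, and for the interaction 9.0%, 73.1% and 97.0%, with 3 false among 122 calls. With no change given, 0 genes were called at 8 h. The simulated noise was independent between genes and had the spread of the arrays without the 2 doubted libraries. These rates are thus for cleaner data than those fitted.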

Results

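NB4 is a human acute promyelocytic leukaemia line that carries the PML-RARA fusion and that all-trans retinoic acid (ATRA) drives toward granulocyte-like cells. The study asked whether a statin alters the genes that go with that differentiation. Atorvastatin blocks the enzyme that makes mevalonate, the precursor of cholesterol. Cells received ATRA, atorvastatin, both agents (combination) or neither (control) for 8, 24 or 48 h, with ATRA given 1 h before atorvastatin. Each of the 12 groups holds 3 arrays, 1 from each of 3 independent experiments, 36 arrays in all. Each array reports 47293 probes, and 15308 genes were tested with limma on normalized log2 signals, where the 50th percentile of all probes is 6.34 and the 90th is 8.59. Genes whose control mean lies near 6.34 were close to background, so their log2 changes are compressed. The raw median signal ran from 78.5 to 185.4 across arrays. The 6 arrays of experiment 1 without ATRA had medians of 152.2 to 185.4, against 101.8 to 118.2 for the 6 arrays of that experiment with ATRA. The number of arrays, 3 per group, limits the precision of every value below, and changes are log2 differences ± SE from limma with n = 3 arrays per group unless a group mean ± SD is named.

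The 2 libraries of experiment 1 at 24 h that are labelled ATRA and atorvastatin each resembled the other label. NCF1, which encodes a subunit of the phagocyte NADPH oxidase, had a signal of 7.88 in the library labelled ATRA and of 13.81 and 13.95 in the other 2 ATRA libraries at 24 h. In the library labelled atorvastatin it was 13.66, against 7.49 and 7.37 in the other 2. KLF2, a transcription factor of endothelial and myeloid cells, stood at 8.51 in the library labelled ATRA and at 6.49 in the one labelled atorvastatin, while the other ATRA libraries had 6.49 and 6.44 and the other atorvastatin libraries 8.88 and 9.11. Both libraries were kept as labelled in all values below, and the number of genes changed in each comparison is also given without them, a choice made after the data were seen. All 36 arrays share 1 estimate of each gene's spread. These 2 libraries therefore widen the SE of genes that ATRA or atorvastatin moves at 8 and 48 h as well as at 24 h. At 24 h they also move the changes themselves in every contrast that uses the ATRA or the atorvastatin group. Those changes, where given with all arrays, may thus differ in size from the effect of the agent named.

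**Figure D1:**
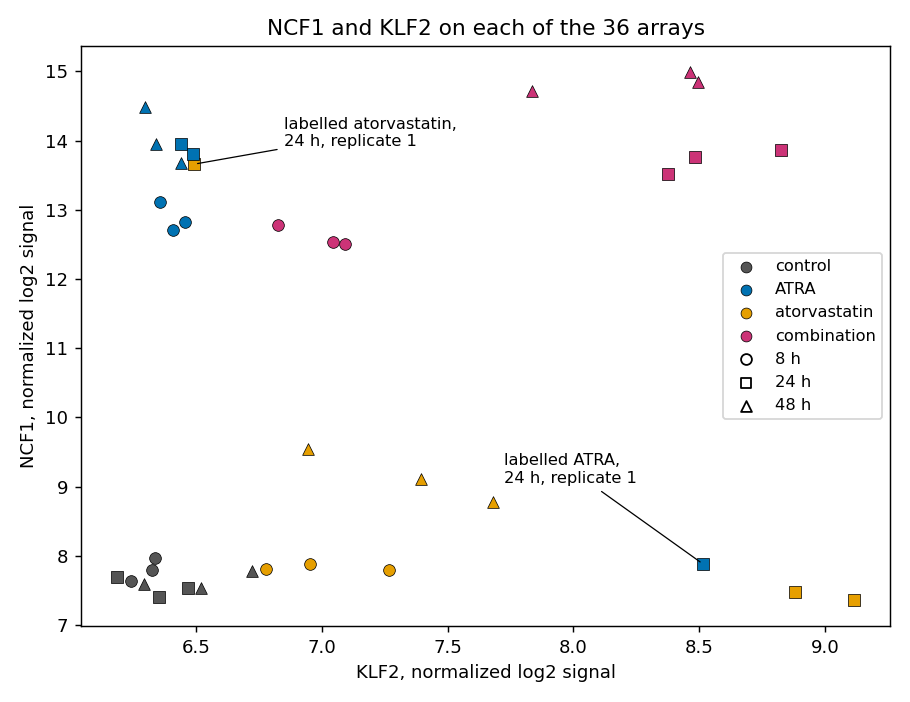
Normalized log2 signal of NCF1 (vertical) against KLF2 (horizontal) on each of the 36 arrays, coloured by labelled group and shaped by time. The library labelled ATRA at 24 h (NCF1 7.88, KLF2 8.51) lies with the atorvastatin libraries, and the one labelled atorvastatin (NCF1 13.66, KLF2 6.49) with the ATRA libraries.

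ATRA against control asks which genes the retinoid moves alone. After 8 h NCF1 had risen by 5.08 ± 1.02, from a control mean of 7.80 ± 0.16 (SD) to 12.88 ± 0.21. Retinoid target genes rose with it, DHRS3, a retinaldehyde reductase, by 2.90 ± 0.58 and ASB2, a ubiquitin ligase subunit known as a retinoid target in this leukaemia, by 2.99 ± 0.65. CD38 rose by 1.66 ± 0.40 and CEBPE, a regulator of late granulocyte genes, by 1.58 ± 0.42. The largest falls were those of BCL11A (-1.58 ± 0.20), TENT5A (-1.43 ± 0.21), INHBB (-1.40 ± 0.27) and IRX3 (-1.37 ± 0.18), and MYC fell by 1.10 ± 0.18. In all, 217 genes changed at 8 h (130 higher and 87 lower, 87 of them by at least 1 log2 unit). Without the 2 doubted libraries the count was 409 (240 higher and 169 lower), and without the arrays of experiment 2 it was 18. It was 238 without those of experiment 1, which takes out both doubted libraries, while leaving out experiment 2 keeps them. With median scaling 77 of 109 genes were higher.

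At 24 h NCF1 was higher by 4.34 ± 1.02 with all arrays and by 6.33 without the 2 doubted libraries. THBD, the thrombomodulin gene, rose by 2.55 ± 0.32, the apoptosis inhibitor gene BCL2A1 by 2.49 ± 0.53 and the gluconeogenic gene FBP1 by 2.18 ± 0.52. MS4A7 (-1.87 ± 0.39) and IGFBP4 (-1.36 ± 0.25) fell. The count was 92 genes (70 higher and 22 lower), 622 without the 2 doubted libraries (399 higher and 223 lower), 496 without the arrays of experiment 1 and 1 without those of experiment 2. With median scaling 330 of 334 genes were higher. ASB2 had an adjusted p of 0.089 in limma with all arrays and of 2.9e-17 without the 2 doubted libraries.

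By 48 h ALOX5AP, needed to make leukotrienes, had risen by 6.74 ± 0.97, NCF1 by 6.40 ± 1.02, the surface antigen gene CD52 by 5.69 ± 0.84, ASB2 by 4.92 ± 0.65 and the monocyte attractant gene CCL2 by 4.79 ± 0.73. S100A8, which encodes a calcium-binding protein of mature neutrophils, rose by 3.42 ± 0.27 and the integrin gene ITGAX by 2.23 ± 0.30, and the integrin gene ITGAM rose from 6.62 ± 0.31 to 8.62 ± 0.08 (SD). Genes of the promyelocyte's primary granules went the other way, CTSG (cathepsin G) falling from 13.83 ± 0.38 to 10.23 ± 0.22 (SD), a change of -3.59 ± 0.33, and MPO changing by -1.07 ± 0.22. IGFBP4 (-2.72 ± 0.25), ASS1 (-2.62 ± 0.34) and VIM (-2.59 ± 0.42) also fell. The count was 1228 genes, 621 higher and 607 lower, and 1467 without the 2 doubted libraries (727 higher and 740 lower). It was 541 without the arrays of experiment 2. With median scaling 629 of 779 genes were higher (80.7%), so the split by direction depends on the scaling.

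Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01. With ATRA at 48 h, 15 of the 22 retinoid response genes measured were higher (17 adjusted over the list alone), with a median of 1.34 and an adjusted p of 8.3e-18. In the granulocyte maturation list 11 of 28 were higher (14 adjusted over the list alone; median 0.31, adjusted p = 1.6e-11), and in the azurophil granule list 6 of 11 were lower and 1 higher (the same numbers adjusted over the list alone; median -1.07, adjusted p = 1.1e-06). The interferon response list had 16 of 28 genes higher (21 adjusted over the list alone), led by OAS3 at 3.12 ± 0.51 and IFI6 at 2.41 ± 0.40. Its median was 1.11 and its adjusted p 4.7e-16, but 0.0886 with an estimated correlation. OAS3 varied by a SD of 1.56 among the ATRA arrays, the highest being the third at 11.46. Among apoptosis regulators 7 of 22 were higher and 1 lower (the same adjusted over the list alone), with a median of 0.24 and an adjusted p of 0.00013, BCL2 changing by -1.90 ± 0.27 and BCL2A1 rising by 4.01 ± 0.53. The MYC and ribosome biogenesis list had 5 of 18 genes lower (7 adjusted over the list alone; median -0.32, adjusted p = 6.5e-05), or 1 with median scaling (median -0.17, adjusted p = 0.00785). In the integrated stress and unfolded protein response list 4 of 20 were lower (4 adjusted over the list alone; median -0.29, adjusted p = 0.0053, or 0.349 with an estimated correlation), among them XBP1 (-1.33 ± 0.23), and 1 with median scaling. The other-cell-type lists did not shift: lymphoid markers had an adjusted p of 0.535 with CD79A higher by 2.22 ± 0.40 and 2 genes lower (3 lower adjusted over the list alone), epithelial and stromal markers 0.562 with PECAM1 higher by 0.65 ± 0.16 (1 gene adjusted over the list alone), and erythroid markers 0.863 with 0 of 8 genes changed in limma and 0 adjusted over the list alone.

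Atorvastatin against control asks what the statin moves alone. At 8 h 1 gene passed the threshold, ZC3HAV1, which encodes an antiviral zinc-finger protein, higher by 1.31 ± 0.20 (9.83 ± 0.16 in control and 11.14 ± 0.09 with atorvastatin, SD). The count was 3 without the 2 doubted libraries, 0 with the mean over each gene's probes and 0 without the arrays of experiment 1, and 395 genes had an unadjusted p under 0.05. The gene has 3 probes, and the call is that of the brightest. At 24 h THBD rose by 2.03 ± 0.32 (1.43 without the 2 doubted libraries), the urokinase gene PLAU by 1.14 ± 0.13 and the AP-1 gene JUND by 0.98 ± 0.13, while ZNF438 fell by 0.86 ± 0.16. These 4 were all that passed, against 50 without the 2 doubted libraries (46 higher and 4 lower), 81 without the atorvastatin array of experiment 2 and 2 without the arrays of experiment 3. KLF2 was higher by 1.82 ± 0.41, short of the threshold with an adjusted p of 0.10, and by 2.66 without those libraries (adjusted p = 1.5e-11). HMGCS1, which makes the precursor of mevalonate, was higher by 0.41 ± 0.33 (adjusted p = 0.89) and by 1.07 without them (adjusted p = 7.9e-05).

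The statin alone changed more genes at 48 h than at 8 or 24 h, with all arrays and without the 2 doubted libraries. The calcium-binding protein genes S100A6 and S100A4 rose by 2.16 ± 0.26 and 2.14 ± 0.16, the matrix protease gene MMP9 by 1.95 ± 0.25, ANXA1 (annexin, an anti-inflammatory protein of phagocytes) by 1.94 ± 0.33 and the cell-cycle inhibitor gene CDKN1A by 1.70 ± 0.21. IL32 rose by 1.40 ± 0.19, the Fc receptor chain gene FCER1G by 1.47 ± 0.24 and ITGAM by 1.05 ± 0.26. EGR1, an immediate early transcription factor, fell by 2.16 ± 0.22, from 10.24 ± 0.28 to 8.08 ± 0.59 (SD), and falls were also seen in the adrenomedullin gene ADM (-1.64 ± 0.22), the cholesterol exporter gene ABCA1 (-1.49 ± 0.22) and MYC (-0.88 ± 0.18). The count was 118 genes, 76 higher and 42 lower, against 261 without the 2 doubted libraries (172 higher and 89 lower) and 22 without the arrays of experiment 2. Median scaling gave 21 genes, 11 of them higher (52.4%).

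Among the cholesterol synthesis and uptake genes at 48 h of atorvastatin, 0 of 20 passed in limma over all genes, 8 were higher when adjusted over the list alone, and 6 over all genes without the 2 doubted libraries. Their median was 0.41 (adjusted p = 4.9e-10, or 0.0663 with an estimated correlation), with HMGCS1 higher by 1.13 ± 0.33 (adjusted p = 0.098). Over all genes 1722 had an unadjusted p under 0.05. In the coagulation and fibrinolysis list 3 of 10 were higher (4 adjusted over the list alone; median 0.56, adjusted p = 0.0002), and 0 in limma with median scaling (adjusted p of the list 0.0024). The fatty acid synthesis list had 1 of 13 higher (3 adjusted over the list alone; median 0.27, adjusted p = 0.0012, or 0.0877 with median scaling), ELOVL6 at 1.04 ± 0.15. The cholesterol efflux and LXR target list had ABCA1 lower and a median of -0.20 over 8 genes (3 lower adjusted over the list alone; adjusted p = 0.0053). Glycolysis had 1 of 16 lower, HK2 by -0.80 ± 0.17 (3 adjusted over the list alone; median -0.22, adjusted p = 0.00103, or 0.136 with an estimated correlation). Heat shock and oxidative stress genes had a median of 0.24 with 0 of 19 past the threshold and 0 adjusted over the list alone (adjusted p = 0.0153, or 0.203 with an estimated correlation and 0.627 with median scaling).

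Combination against control asks what both agents do together. At 8 h NCF1 was higher (4.80 ± 1.02) and BCL11A lower (-1.61 ± 0.20), as with ATRA alone, with ZC3HAV1 higher by 1.40 ± 0.20. The count was 199 (102 higher and 97 lower), 405 without the 2 doubted libraries and 24 without the arrays of experiment 2, and median scaling gave 137 higher of 153. At 24 h NCF1 stood 6.17 ± 1.02 higher, FBP1 4.06 ± 0.52, THBD 3.90 ± 0.32, KLF2 2.22 ± 0.41 and ADGRE5, an adhesion receptor of leukocytes, 1.67 ± 0.15, among 922 changed genes (537 higher and 385 lower, or 1159 without the 2 doubted libraries, 671 higher and 488 lower). That count was 257 without the arrays of experiment 2. Median scaling gave 1003 genes at 24 h, 95.2% of them higher.

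At 48 h of both agents ALOX5AP was higher by 7.58 ± 0.97, NCF1 by 7.21 ± 1.02, G0S2, a lipase inhibitor gene, by 5.81 ± 0.45, S100A8 by 5.22 ± 0.27, THBD by 5.16 ± 0.32 and ITGAM by 3.93 ± 0.26. IL1B, the interleukin gene of activated phagocytes, rose by 4.64 ± 0.16, from 6.37 ± 0.03 in control to 11.01 ± 0.16 (SD). Lower were the granule genes CTSG (-4.45 ± 0.33), CST7 (-3.37 ± 0.32) and MPO (-1.78 ± 0.22) and the early myeloid gene MS4A3 (-2.97 ± 0.25). MYC fell by 2.51 ± 0.18, from 13.00 ± 0.24 to 10.48 ± 0.10 (SD). In total 3118 genes changed, 1480 higher and 1638 lower, 764 by at least 1 log2 unit. Without the 2 doubted libraries it was 3275 (1546 higher and 1729 lower), and without the arrays of experiment 2 it was 1836. With median scaling 2445 of 2784 genes were higher (87.8%), the median of all 15308 genes moving by 0.10, so the split by direction depends on the scaling.

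In the combination at 48 h 19 of 28 granulocyte maturation genes were higher (19 adjusted over the list alone; median 0.92, adjusted p = 1.7e-14) and 17 of 18 MYC and ribosome biogenesis genes were lower (17 adjusted over the list alone; median -0.96, adjusted p = 2.15e-14), or 9 with median scaling (median -0.58, adjusted p = 5.7e-10). Among chemokines and inflammatory cytokines 14 of 23 were higher (14 adjusted over the list alone; median 1.29, adjusted p = 3.7e-10) and among interferon response genes 23 of 28 (24 adjusted over the list alone; median 1.32, adjusted p = 1.6e-13, or 0.133 with an estimated correlation). The immediate early and KLF list had 6 of 16 higher and 1 lower (7 higher adjusted over the list alone; adjusted p = 0.0128, or 0.169 with an estimated correlation and 0.116 with median scaling), with JUND up by 2.14 ± 0.13, ZFP36 by 1.32 ± 0.15 and EGR1 down (-1.75 ± 0.22). Cell cycle genes did not shift as a list, with 2 of 28 higher and 5 lower, a median of -0.12 and an adjusted p of 0.192.

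**Figure D2:**
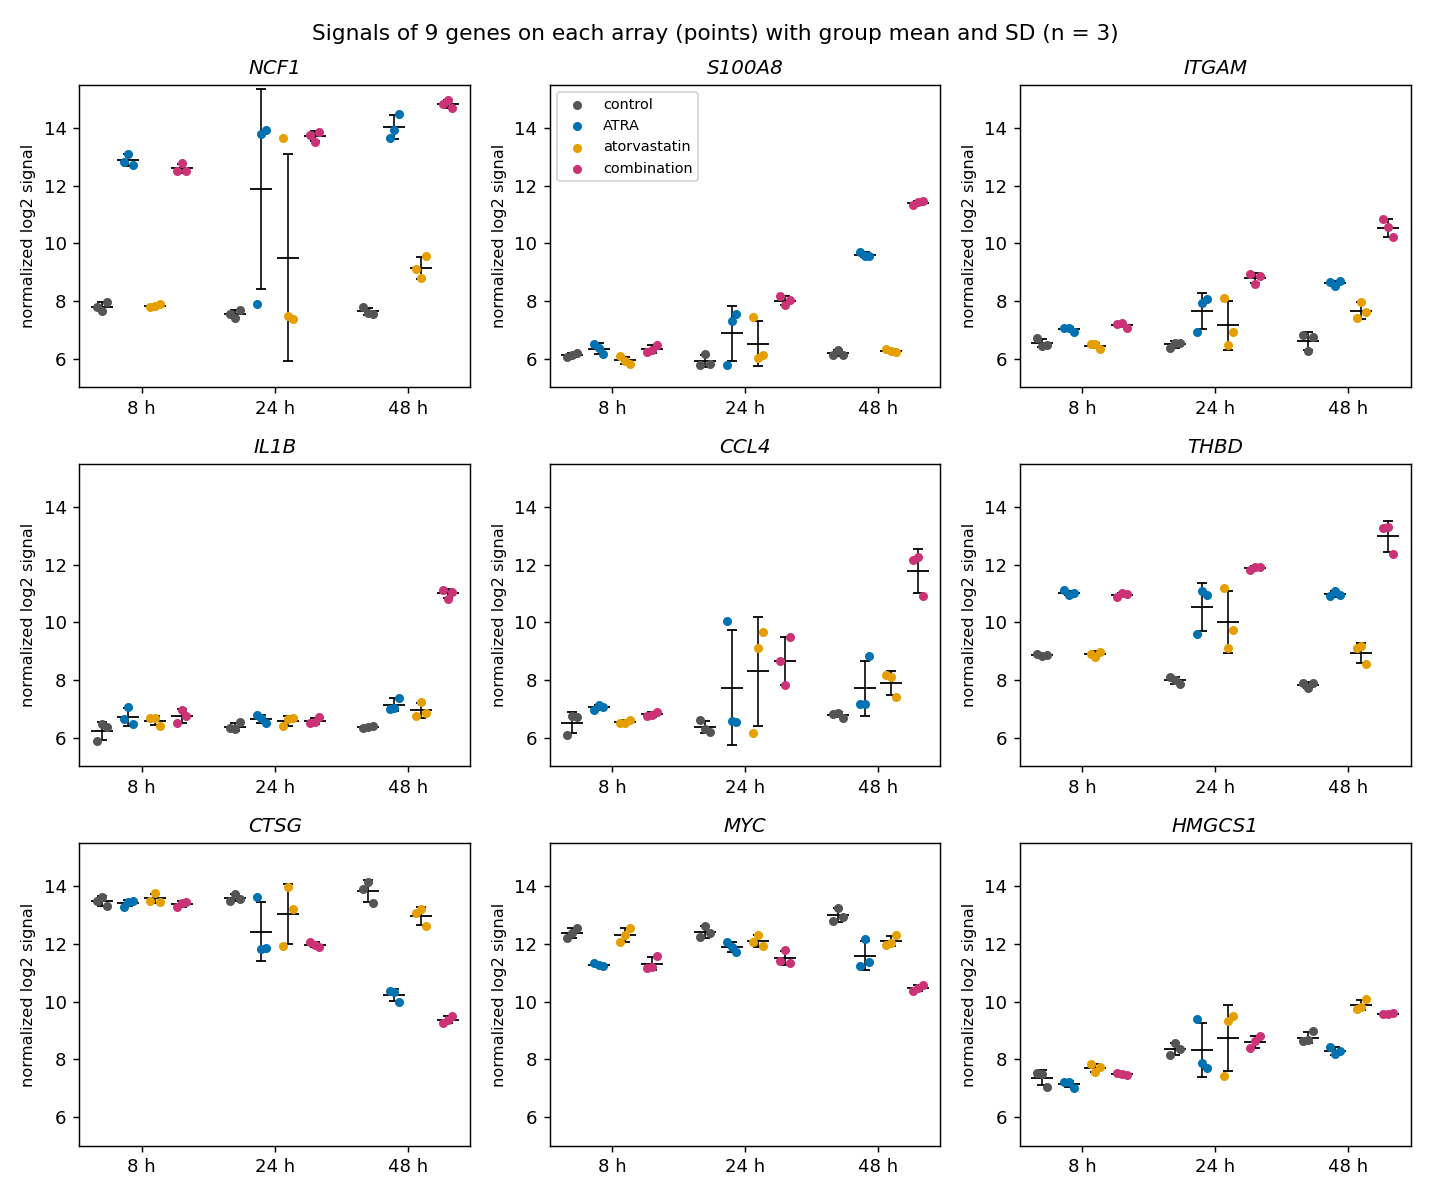
Normalized log2 signal of 9 genes on each array, by time and labelled group, with the group mean and SD (n = 3). At 48 h IL1B averages 6.37 in control, 7.14 with ATRA, 6.95 with atorvastatin and 11.01 with both, while CTSG and MYC are lowest with both (9.38 and 10.48), and the wide SDs of NCF1 at 24 h come from the 2 doubted libraries.

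Combination against ATRA asks what atorvastatin adds in cells that already have the retinoid. At 8 h ZC3HAV1 alone passed, higher by 1.46 ± 0.20, although the gene's other 2 probes gave changes between -0.22 and 0.27, and the count was 3 without the 2 doubted libraries and 0 in limma with the mean over each gene's probes (373 genes had an unadjusted p under 0.05 with the probe used). At 24 h ADGRE5 (1.21 ± 0.15) and PLAU (0.78 ± 0.13) passed, against 33 genes without the 2 doubted libraries (31 higher and 2 lower), 7 with the experiment as a block and 0 without the arrays of experiment 2. At 48 h the chemokine genes CCL4, CCL3L1 and CCL3 were higher by 4.07 ± 0.65, 3.70 ± 0.51 and 3.56 ± 0.48, IL1B by 3.87 ± 0.16, FCER1G by 3.34 ± 0.24 and the complement receptor gene C5AR1 by 2.84 ± 0.30. VIM, which ATRA lowered, was higher by 2.24 ± 0.42, ITGAM by 1.93 ± 0.26, KLF2 by 1.90 ± 0.41, S100A8 by 1.80 ± 0.27 and HMGCS1 by 1.30 ± 0.33. PHACTR3 (-1.22 ± 0.15), DEFB1 (-1.19 ± 0.16) and MYC (-1.12 ± 0.18) were lower. SNRNP200 (-2.25 ± 0.63) and REPIN1 (-1.65 ± 0.45) were lower, each through 1 combination array, the third, at 5.69 and 5.68. The count was 979 genes, 523 higher and 456 lower, against 1162 without the 2 doubted libraries (627 higher and 535 lower) and 246 without the arrays of experiment 2. With median scaling 761 of 787 genes were higher (96.7%).

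By list, atorvastatin on top of ATRA at 48 h raised 10 of 23 chemokines and inflammatory cytokines (12 adjusted over the list alone; median 0.44, adjusted p = 1.6e-13), 11 of 28 granulocyte maturation genes (12 adjusted over the list alone; median 0.33, adjusted p = 8.4e-08), 6 of 10 coagulation and fibrinolysis genes (7 adjusted over the list alone; median 0.83, adjusted p = 6.4e-09) and 3 of 10 monocyte and macrophage genes (3 adjusted over the list alone; median 0.22, adjusted p = 0.00011), the ficolin gene FCN1 by 1.83 ± 0.15. MYC and ribosome biogenesis genes were lower in 13 of 18 cases (16 adjusted over the list alone; median -0.68, adjusted p = 6.5e-16), POLR1B by -0.95 ± 0.13 and NOP56 by -0.79 ± 0.17. With median scaling 2 of the 18 were lower (median -0.45, adjusted p = 3.8e-10), so the count rests on the scaling. Of the retinoid response genes 2 of 22 were higher (2 adjusted over the list alone), CYP26B1 at 0.81 ± 0.25 and STRA6 at 1.75 ± 0.28, with a list median of -0.02 and an adjusted p of 0.439, where the camera test points up and the median down. Among cholesterol synthesis and uptake genes 3 of 20 were higher (7 adjusted over the list alone; median 0.43, adjusted p = 2e-05, or 0.224 with an estimated correlation).

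**Figure D3:**
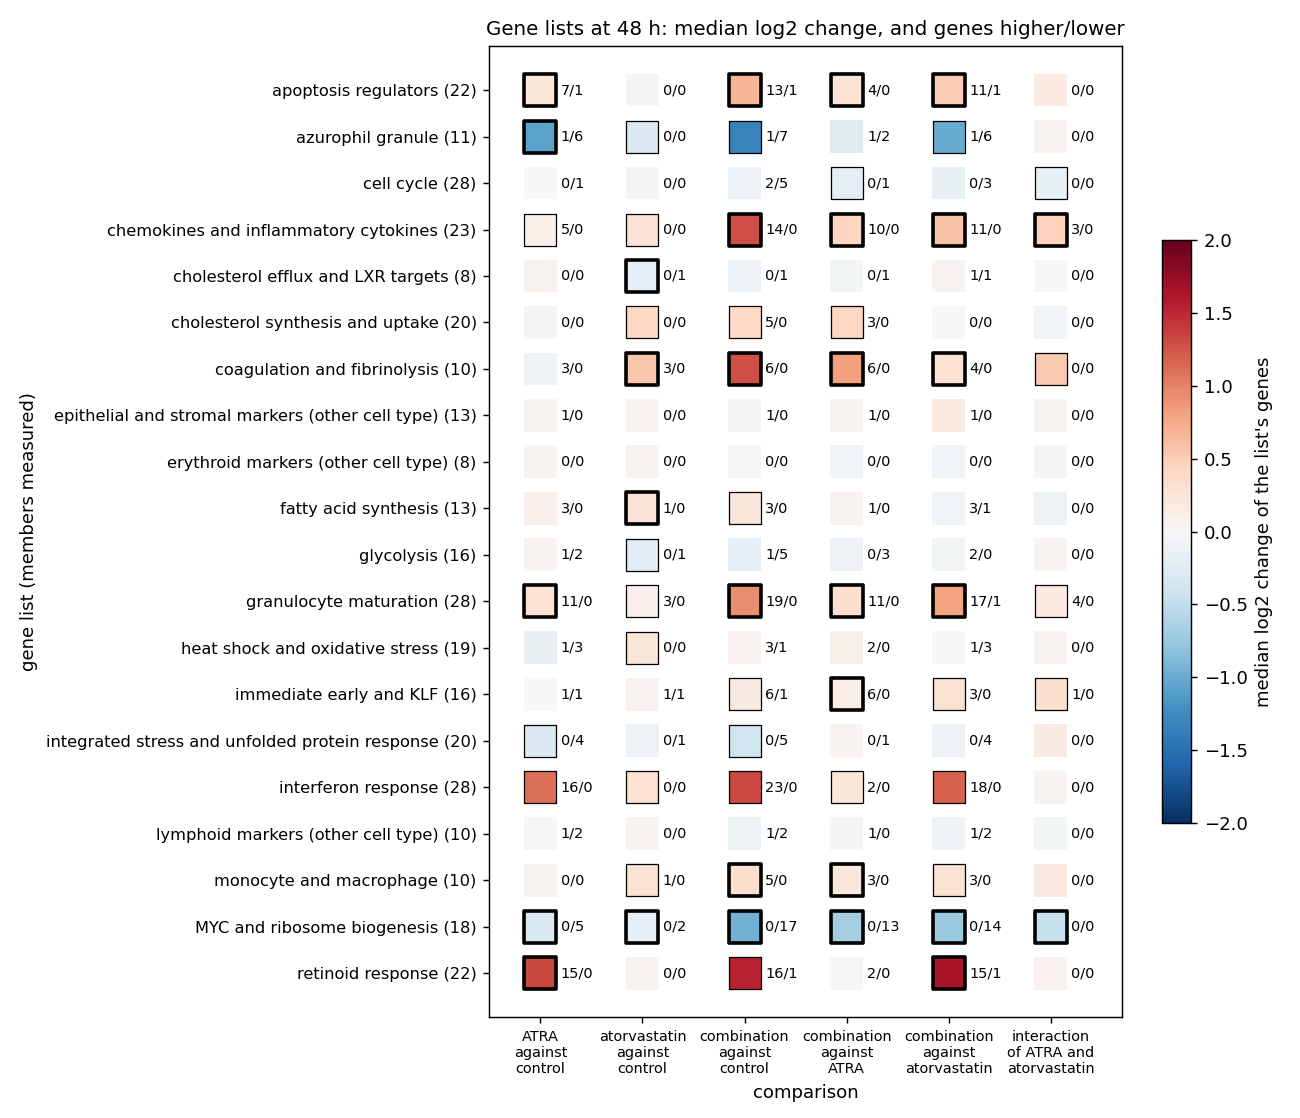
Median log2 change at 48 h of each gene list (colour) in each comparison, with the numbers of genes higher and lower beside it, a black edge where camera's adjusted p is under 0.05 and a thick edge where it is also under 0.05 with an estimated correlation. Retinoid response genes rise with ATRA (median 1.34) and MYC and ribosome biogenesis genes fall furthest in the combination (median -0.96).

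Combination against atorvastatin asks what ATRA adds in cells that have the statin. At 48 h ALOX5AP was higher by 6.58 ± 0.97, G0S2 by 5.96 ± 0.45, NCF1 by 5.70 ± 1.02, PTGES, which makes prostaglandin E, by 5.49 ± 0.40 and the kinase gene FGR by 5.13 ± 0.67. CTSG was lower (-3.60 ± 0.33), as was MMP9, which the statin alone raised (-1.45 ± 0.25). The count was 177 genes at 8 h (95 higher and 82 lower, 367 without the 2 doubted libraries, 17 without the arrays of experiment 2), 226 at 24 h (186 higher and 40 lower, 856 without the 2 doubted libraries, 0 without the arrays of experiment 2) and 2258 at 48 h (1082 higher and 1176 lower, 2436 without the 2 doubted libraries, 1231 without the arrays of experiment 2). With median scaling 147 of 157 genes were higher at 8 h, 983 of 987 at 24 h and 95.7% of 3132 at 48 h.

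The interaction of ATRA and atorvastatin asks whether the statin's effect differs between cells with and without ATRA. At 48 h IL1B had the largest interaction, 3.29 ± 0.23 (adjusted p = 1.2e-11), followed by CCL3L1 (2.96 ± 0.71), PTGES (2.73 ± 0.57), RIPOR2 (2.12 ± 0.27), C5AR1 (2.11 ± 0.43) and FCER1G (1.87 ± 0.34). PTGES stood at 6.79 ± 0.19 in control, 9.55 ± 0.20 with ATRA, 6.26 ± 0.09 with atorvastatin and 11.75 ± 0.11 with both (SD). IL32 ran the other way, with an interaction of -1.42 ± 0.27: the statin raised it to 8.81 ± 0.08 from 7.41 ± 0.11 (SD) without ATRA and left it at 7.12 ± 0.13 against 7.14 ± 0.23 with ATRA. With median scaling its interaction was -1.03 ± 0.29 (adjusted p = 0.0947). In all 79 genes passed, 69 higher and 10 lower, against 161 without the 2 doubted libraries (137 higher and 24 lower) and 5 without the arrays of experiment 2. Of the 69 higher, 62 were also above control in the combination, and 46 passed for neither agent alone. No gene passed in limma, with or without those libraries, at 8 h (398 with an unadjusted p under 0.05, or 427 without them) or at 24 h (390, or 533 without them). With median scaling 156 of 157 genes were higher, the median of all genes moving by 0.16, and 67 of the 69 higher genes and 0 of the 10 lower ones were called, so the split by direction rests on the scaling.

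The chemokine and inflammatory cytokine list shifted up in the interaction at 48 h with 3 of 23 genes past the threshold (7 adjusted over the list alone; median 0.46, adjusted p = 6.4e-09), and MYC and ribosome biogenesis genes shifted down with 0 of 18 past it (0 adjusted over the list alone; median -0.46, adjusted p = 4.3e-07). With median scaling the latter had a median of -0.073 and an adjusted p of 0.0802. The 70 genes that ATRA raised at 24 h had a median interaction of 0.18 at 48 h (camera p = 0.00024, or 0.409 with an estimated correlation), 72.9% of them above 0. Without the 2 doubted libraries the set held 399 genes with a median of 0.077, 60.2% of them above 0 (camera p = 4.8e-05, or 0.095 with an estimated correlation). The 621 raised at 48 h had a median interaction of 0.0064 at 24 h, 52.0% of them above 0, and did not pass the same test. Across genes, which are not independent replicates, the ATRA effect without atorvastatin and that with it had a Pearson r of 0.77 at 48 h (Spearman 0.50, slope 0.92). For the statin's effect without and with ATRA, r was 0.41 (Spearman 0.30, slope 0.52). That effect had a SD across genes of 0.24 without ATRA and 0.30 with it, so the slope does not show a smaller effect with ATRA.

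**Figure D4:**
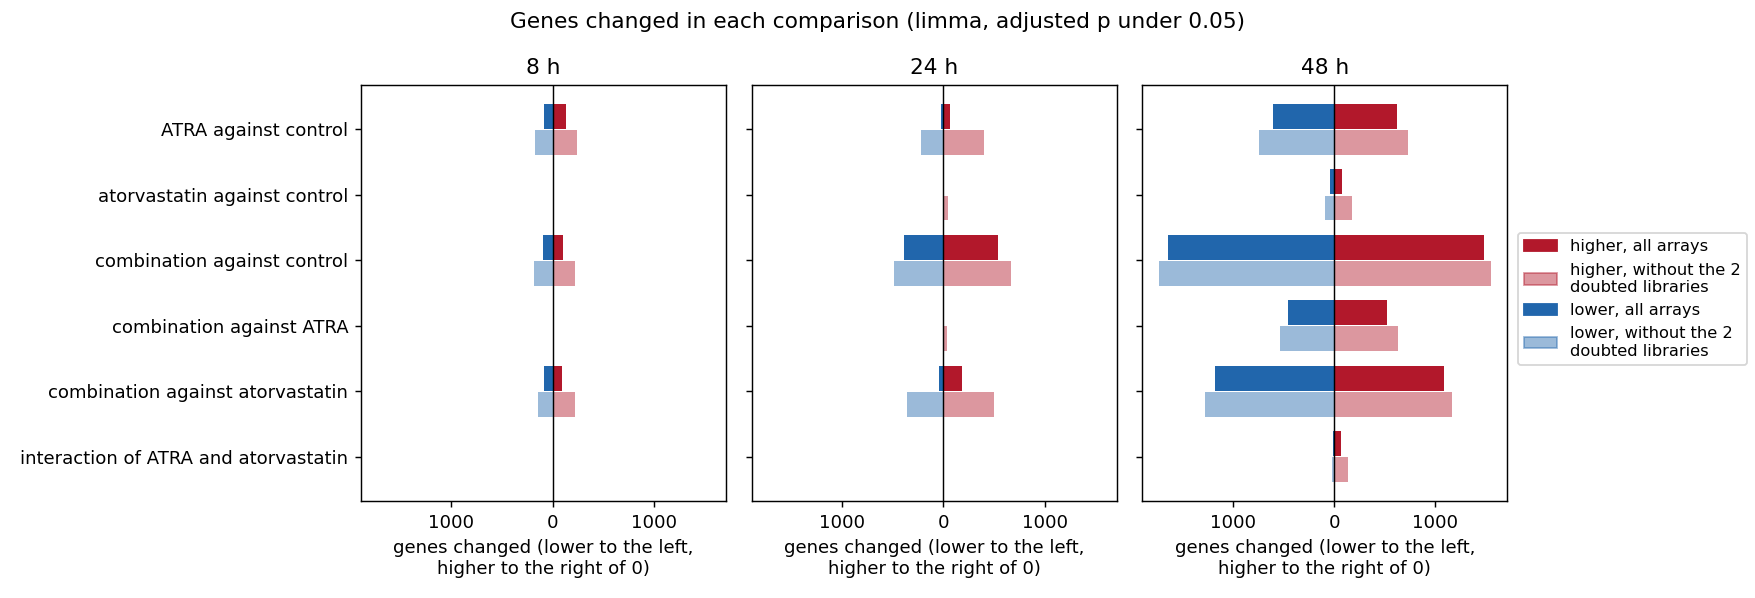
Genes changed in each comparison (limma, adjusted p under 0.05), lower to the left and higher to the right of 0, with all arrays (dark) and without the 2 doubted libraries (pale). The combination against control at 48 h has the most (1480 higher and 1638 lower), and at 24 h ATRA goes from 92 to 622 and combination against atorvastatin from 226 to 856 when the 2 libraries are left out.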

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

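The tests of an exchange of the 2 libraries, of a failed treatment, of removing a background, of no background correction, of median scaling and of permuted residuals were chosen only after the result was seen, while the batch and brightness tests, the comparison with the authors' values and the counts over other splits of the arrays were set beforehand.

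At 48 h the effect of atorvastatin differed between cells with and without ATRA, by the test of the interaction itself, for 16 named genes. The statin's effect was more positive in the presence of ATRA for 11 of them, with interactions of 3.29 for IL1B, 2.96 for CCL3L1, 2.73 for PTGES, 2.12 for RIPOR2, 2.11 for C5AR1, 1.87 for FCER1G, 1.84 for CCL20, 1.71 for S100A8, 1.18 for ADGRE5 and 1.05 for CCL7. The eleventh, EGR1, had an interaction of 1.59, the statin changing it by -2.16 ± 0.22 without ATRA and by -0.57 ± 0.22 with it. The interaction was negative for IL32 (-1.42), PALD1 (-1.20), CCDC85B (-1.16), HPDL (-1.08) and PHB1, a mitochondrial prohibitin gene (-1.02), none of the 5 past the threshold with median scaling. IL32 was raised by atorvastatin alone, and at 48 h the other 4 passed the threshold in the contrasts of the combination and in neither agent alone.

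Background on the log scale was weighed as a technical cause, since a gene at the floor without ATRA cannot show a small change. Of the 79 interaction genes, 16 were bright in the control, ATRA and atorvastatin groups, above the 90th percentile of all probes (8.59), 10 of them higher and 6 lower, so a floor does not account for these 16. CCL20 (9.23 in control, 9.34 with ATRA, 8.61 with atorvastatin and 10.56 with both) and PALD1 (9.60, 9.50, 9.80 and 8.50) are among them. Of the other 63, 18 kept their interaction beyond 3 SE at each background removed, up to the lowest of the gene's 12 group means or the 75th percentile of all probes (6.62), whichever is lower. Of these, 5, IL1B among them, had a mean below 6.62, near background, in the control, ATRA or atorvastatin group at 48 h. The other 13, 9 higher and 4 lower, IL32 among them, did not, so a floor up to the highest background removed does not account for these 13. For JAK2, among the 13, that background was 6.59, the lowest of its 12 group means. The limits at the 75th percentile were set after values of this test were seen. For the remaining 50, IL1B included, a floor and a joint effect of the agents cannot be told apart, because a group lies near background or the interaction came within 3 SE or was undefined once a background was removed. EGR1, with group means of 8.08 to 10.24, had an interaction of at least 1.59 at each background removed, but of 2.77 SE at the lowest.

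Background correction is argued against as the cause of the interaction, since 100% of the 79 genes were called with the same sign without it. All 79 were also called with the same sign in the authors' own log2 values (100%), but these have nearly the same median on every array and so do not test normalization. With median scaling 97.1% of the 69 higher genes were called with the same sign. With the shift of all genes (0.16) taken off, 68 lay beyond 3 SE. That setting moved higher and lower genes alike upward, and by more than it moved all genes. The median of the 69 went from 1.17 to 1.47, and that of the 10 bright ones among them from 1.07 to 1.46. Such a move favours calls of higher genes, so median scaling cannot decide whether normalization made them. Of the 10 lower genes 0% were called, 6 of the 16 bright genes among them. With the same shift taken off, 3 of the 10 lay beyond 3 SE. All 10 stayed negative. Their median went from -0.99 to -0.60, IL32 from -1.42 ± 0.27 to -1.03 ± 0.29 and PALD1 from -1.20 ± 0.23 to -0.74 ± 0.28 (SE), so the calls ended through smaller changes and wider SE, and normalization stays open as their cause.

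Of 100 splits of the 12 arrays at 48 h, 14 gave as many genes as the real 79, the highest 771, so this count does not exclude chance. It does not stand for the absence of an interaction, since a split that turns the statin labels in 1 arm carries the statin's own effects into the contrast by construction, and it ignores the experiments. Of the 48 splits that turned the labels 6 reached 79 genes (highest 771), and of the 51 that did not 7 did (highest 252). Both highest counts are several times the real one. A split that did not turn the labels could still keep unlike numbers of statin arrays in each arm, and so carry part of the statin's effects. The counts therefore cannot tell those effects from another structure of the samples. With the additive effects of the agents removed and the residuals permuted over the 12 arrays, 1 of 100 draws, the real one, gave as many as 79 genes (highest other 29). Within experiments, and with the experiment as a block, 3 of 100 gave as many as the real 127 (highest other 195). Both draws argue against chance for the number of interaction genes at 48 h. At 8 and 24 h 0 genes passed in limma (398 and 390 with an unadjusted p under 0.05), so that 100 of 100 splits reach that number by construction (highest 2 and 22) and the count decides nothing. For the 10 bright genes that were higher, and the 9 others above, a joint action of atorvastatin and ATRA remains a hypothesis. It was found and tested on the same arrays, and normalization stays open as another cause.

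For each of the 2 libraries, the change from the control mean at 24 h was correlated across genes with that of other libraries. The comparison was with the mean change of the other 2 libraries of a label. For the library labelled ATRA at 24 h in experiment 1, r was 0.17 with ATRA and 0.43 with atorvastatin. For the library labelled atorvastatin these were 0.73 and 0.08. Both of the 2 libraries were nearer to the partner's label, which is consistent with an exchange somewhere between culture and array. The ATRA score was the mean signal of the 1082 genes higher minus that of the 1176 lower in combination against atorvastatin at 48 h. It was taken relative to control cells of the same time. The library labelled atorvastatin had 96.3% of the score of the other ATRA libraries. This argues against a failed or weak treatment of single cultures, since no culture given atorvastatin alone was to receive ATRA. The higher raw signal of the 6 arrays of experiment 1 without ATRA is argued against too, as the highest ATRA score of the other 5 was 4.82% of that of the ATRA libraries of the same time. The library labelled atorvastatin had a raw median of 178.9, within the 152.2 to 185.4 of experiment 1 without ATRA. The one labelled ATRA had 118.2, just above the 101.8 to 117.3 of the other arrays of that experiment with ATRA and below all of those without it. An exchange of scanned data would have moved these medians as well, so they argue against it. Whether an exchange, if it took place, was of cultures, RNA or records before the arrays stays open. No biological explanation was tested because the design gives none.

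Probes without a gene symbol took no part in the comparisons. Of 24419 such probes past the filter, 355 changed in the combination against control at 48 h (1.45%, 193 higher and 162 lower), against 20.4% of the 15308 named genes. In ATRA against control at 48 h it was 129, and in atorvastatin against control 4. What these probes measure was not tested.

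For each comparison of 3 arrays with 3 there are only 10 splits, too few for a share under 0.05, and in each of the 15 the real split was the 1 with the most genes. At 8 h the highest other split gave 0 genes against 217 for ATRA, 1 for atorvastatin, 199 for the combination, 1 for combination against ATRA and 177 for combination against atorvastatin. At 24 h it gave 38 against 92 for ATRA, 1 against 4 for atorvastatin, 0 against 922 for the combination, 0 against 2 for combination against ATRA and 47 against 226 for combination against atorvastatin. At 48 h it gave 0 against 1228 for ATRA, 4 against 118 for atorvastatin, 16 against 3118 for the combination, 38 against 979 for combination against ATRA and 138 against 2258 for combination against atorvastatin.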

How the results depend on the processing

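Leaving out the 2 doubted libraries, the random block, median scaling for the lists and the interquartile range filter were chosen only after the data were seen. Each of the 254 changes of named genes kept its direction under every setting tried, apart from ACLY (0.048) and HRAS (0.13) in combination against atorvastatin at 48 h with median scaling. All 254 stayed past the threshold with the replicate block, the random block, no filter on dim probes and without the 2 doubted libraries, 246 without background correction, 239 with the mean over the probes, 237 in the authors' log2 values, 204 with only the arrays of 1 time and 202 with median scaling. Of the 142 list calls, 63 held with an estimated correlation, 139 with the replicate block, 140 with the mean over the probes, 132 without the 2 doubted libraries and 105 with median scaling, 5 of them with an estimated correlation too. Without those libraries 4 list medians at 24 h reversed, coagulation and fibrinolysis with ATRA (-0.13), retinoid response with atorvastatin (-0.042), and granulocyte maturation (-0.025) and 1 other list (-0.015) in combination against ATRA. Median scaling reversed 8 list medians: retinoid response in combination against ATRA at 8 h (0.0027), MYC and ribosome biogenesis with ATRA (0.084) and heat shock (0.24), integrated stress (0.060) and MYC and ribosome biogenesis (0.13) in combination against atorvastatin at 24 h, heat shock in the interaction at 24 h (0.026), and cell cycle in combination against ATRA (0.034) and in the interaction (0.23) at 48 h. The cause was not tested.

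Counts moved by more than 1.5 times as follows, and the cause was not tested except where a setting uses fewer arrays. Without background correction 60 genes changed with ATRA and 7 with atorvastatin at 24 h. Median scaling gave 109 for ATRA and 0 for atorvastatin at 8 h (limma), 334 for ATRA, 1 for atorvastatin, 6 for combination against ATRA and 987 for combination against atorvastatin at 24 h, and 779 for ATRA, 21 for atorvastatin and 157 for the interaction at 48 h, moving the median of all genes by up to 0.16. The authors' log2 values gave 180 for the interaction at 48 h. The mean over probes gave 0 for atorvastatin and for combination against ATRA at 8 h and 60 for ATRA at 24 h.

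With the experiment as a block, 7 genes changed with atorvastatin at 24 h and 7 in combination against ATRA, 221 with atorvastatin at 48 h and 127 in the interaction. The reported values use no pairing by experiment, because the titles do not state the experiment and not every pair of same-numbered arrays deviated together: 31 of 45 correlated above 0.1 (from -0.14 to 0.44), all 3 pairs in 4 of 15 comparisons, among them combination against ATRA at each time (0.15 to 0.44). By average correlation 29 of 36 arrays were nearest to their own experiment of the 3. This points to a difference between experiments that the reported values leave out. The 2 doubted libraries were kept in these correlations and alter the deviations at 24 h. The lowest value (-0.14) arose there, in combination against atorvastatin. The random block of experiment by ATRA arm (consensus correlation 0.108) gave 12, 13, 225 and 141 for the same results. Without the 2 doubted libraries the counts were 409 (ATRA), 3 (atorvastatin), 405 (combination), 3 (combination against ATRA) and 367 (combination against atorvastatin) at 8 h, 622, 50, 1159, 33 and 856 in that order at 24 h, and 261 for atorvastatin and 161 for the interaction at 48 h. With the block as well they were 518, 3, 555, 3 and 479 at 8 h, 769, 63, 1455, 42 and 1039 at 24 h, and 424 for atorvastatin, 1473 for combination against ATRA and 244 for the interaction at 48 h. In the fit without those libraries, genes that ATRA raised at 24 h had a median interaction of -0.056 at 8 h (camera p = 0.0233, or 0.341 with an estimated correlation), and r between an agent's effects without and with the other at 24 h was 0.75 for ATRA and 0.27 for atorvastatin. With an estimated correlation the genes raised at 24 h (median 0.18 at 48 h) no longer passed. Only the arrays of 1 time gave 516, 3, 538, 2 and 490 at 8 h, 3, 2, 474, 1 and 3 at 24 h, and 62 for atorvastatin and 47 for the interaction at 48 h.

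Leaving out each array or experiment gave, at 8 h, 18 to 238 (ATRA), 0 to 1 (atorvastatin), 24 to 253 (combination), 0 to 1 (combination against ATRA) and 17 to 232 (combination against atorvastatin). At 24 h it gave 1 to 496, 2 to 81, 257 to 686, 0 to 11 and 0 to 726 in that order. At 48 h it gave 541 to 1077, 22 to 232, 1836 to 2880, 246 to 972 and 1231 to 2080, and 5 to 105 for the interaction. The lowest count was without experiment 2 for ATRA, the combination and combination against atorvastatin at each time and for the interaction at 48 h, and the highest at 24 h for ATRA was without experiment 1, whose library labelled ATRA is doubted. At 8 h the highest for ATRA, the combination and combination against atorvastatin was also without experiment 1. Leaving out experiment 2 or 3 keeps both doubted libraries, so the low counts cannot be put down to experiment 2 alone. Without experiment 1, 2 or 3, 233, 154 and 172 of the 254 gene changes stayed past the threshold, with 2 arrays left per group. The negative-control background method, the detection filter of the labels and a chip block were planned and not run, because the files used here give no detection value or chip. Signal near background limits what can be called for dim genes.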

Other observations

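All tests in this part of the control arrays over time, and the genes named from them, were chosen only after the values were seen, while the test of ATRA genes in the atorvastatin arrays was set beforehand.

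The untreated control cells changed with time in culture. From 8 to 48 h EGR1 rose by 3.88 ± 0.22 (SE, n = 3), the growth and stress regulator gene DDIT4 by 2.07 ± 0.20, CXCL8 (an interleukin that attracts neutrophils) by 2.02 ± 0.50, ADM by 1.94 ± 0.22, the pseudokinase gene TRIB3 by 1.60 ± 0.25 and the stress transcription factor gene DDIT3 by 1.58 ± 0.30. The glucose transporter gene SLC2A3 rose by 1.46 ± 0.24, HK1 by 1.26 ± 0.20, and the sterol genes HMGCS1 and DHCR7 by 1.39 ± 0.33 and 1.18 ± 0.24. The sialophorin gene SPN changed by -1.56 ± 0.26 and the heat shock genes HSPA1B, DNAJB1 and DNAJA1 by -1.46 ± 0.23, -0.93 ± 0.19 and -0.93 ± 0.19. In all 550 genes changed (284 higher and 266 lower), or 732 without the 2 doubted libraries, and from 8 to 24 h 0 changed in limma, or 3 without those libraries.

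Among the lists, heat shock and oxidative stress genes had a median of -0.27 at 24 h against 8 h (adjusted p = 8.2e-07, or 0.0208 with an estimated correlation) and cholesterol synthesis and uptake genes one of 0.18 (adjusted p = 0.000109, or 0.428 with an estimated correlation). By 48 h, 10 of 19 heat shock and oxidative stress genes were lower in control cells at 48 h than at 8 h (median -0.56, adjusted p = 1e-13), and 5 of 20 integrated stress and unfolded protein response genes were higher (median 0.43, adjusted p = 8.5e-08, or 0.097 with an estimated correlation). The cholesterol synthesis and uptake list had 4 of 20 higher (median 0.34, adjusted p = 4.9e-06, or 0.291 with an estimated correlation), fatty acid synthesis 3 of 13 (median 0.28, adjusted p = 0.0054), and glycolysis 3 of 16 (median 0.092, adjusted p = 0.0051, or 0.291 with an estimated correlation). In the MYC and ribosome biogenesis list 1 of 18 was lower (median -0.25, adjusted p = 0.0067, or 0.246 with an estimated correlation). EGR1, ADM and HK2 were lower with the statin than in control cells at 48 h, and in control cells they had risen since 8 h, HK2 by 0.97 ± 0.17. A smaller rise with the statin would give the same difference, and treated cells were not tested over time.

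A hypothesis was that atorvastatin alone comes to raise by 48 h the genes that ATRA raises at 8 h. The 130 such genes had a median change of 0.15 with atorvastatin at 48 h, 72.3% of them above 0 and 4 past the threshold (camera p = 3.2e-07, or 0.294 with an estimated correlation). The 87 genes that ATRA lowered at 8 h had a median of -0.22, with 9 lower (camera p = 2.4e-11, or 0.075 with an estimated correlation). The shift may come from genes that move together, so the hypothesis stays open.

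Several genes chosen in advance had low signals at 48 h. CYP26A1 averaged 6.27 in control and 6.84 with ATRA at 48 h, RARB 6.07 and 6.48, and ELANE 6.52 and 6.38, against a median of all probes of 6.34.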
